A study of Mus musculus with 10 samples.

How the data were processed

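Total RNA from inguinal white adipose tissue was sequenced in 10 libraries after ribosomal RNA depletion with a strand-marking library kit, per the labels' protocols. The genotype label put 5 libraries in the control group and 5 in the Tcf7l2 knockout group, written here as control 1 to 5 and knockout 1 to 5. That label reads wild type for the controls, while their titles carry F/F. The titles of both groups write TCF7 or TCF, and the genotype label of the knockouts names Tcf7l2. Replicate numbers were given in the order of the records within each group, so equal numbers pair nothing across the groups. Each title carries a number of its own, read here as a mouse number, and the labels do not say in words that every library came from a separate mouse. If they did not, the p-values measure only the spread between these samples. The high-fat diet lasted 16 weeks per the diet label and the series design, 12 weeks per the sample descriptions and 4 months per the treatment protocol.

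The values used are counts of reads per gene that the authors deposited in a single table for all 10 libraries, whole numbers with no normalization. STAR 2.5.2b, featureCounts 1.5.1, DESeq2 1.16.0 and the GRCm38 genome are named per the submitters' processing notes. The annotation release, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here. Reads of a gene and of a neighbour that overlaps it, on either strand, may therefore have been counted together. Among the genes named in the text, the share of exonic bases that another gene also covers was 47.9% for Atp5o, 30.9% for Irs1, 24.9% for Adrb3, 22.5% for Higd1a, 20.6% for Iglc3, 20.0% for Rpl32, 18.6% for Aldh6a1, 17.9% for Slc7a10, 15.3% for Pkm, 13.7% for Lef1 and 12.8% for Mogat1. Ribosomal protein genes, histone genes, globin genes, immunoglobulin genes and processed pseudogenes have near-identical copies, so their counts are uncertain in the same way.

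Of 52636 gene identifiers, 52403 had a symbol and a position in GENCODE release M21 on GRCm38 and 233 had none. A count above 0 in any library was found for 40157. Total counts ran from 14032866 to 17782073 per library, and a floor of 3 counts corresponded to between 0.169 and 0.214 CPM (counts scaled to a common library total), which covers counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. The 20 pairs of libraries of the same group differed by more than sampling noise, with chi-square values per degree of freedom between 7.17 and 29.6, so each library was counted as 1 replicate.

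All tests ran in R 4.3.3. Genes were filtered with filterByExpr by group, which left 15927 (28 of them without a symbol), and scaled with TMM factors. The 2 groups were compared with the two-sided quasi-likelihood test of edgeR 4.0.16 with no covariate, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method. A gene is called changed at an adjusted p below 0.05, and a positive log2 fold change means higher in the knockout. Values per library are TMM-scaled CPM. For Tcf7l2 and for scores, a two-sided exact permutation test ran over all 252 ways to choose 5 of the 10 libraries, and 0.0079 is the smallest p that it can give. With this design, simulated changes of 1.5-fold in 200 genes were recovered in 57% of cases, changes of 2-fold in 78% and changes of 1.3-fold in 9%, with 12, 6 and 0 false calls. Simulated data with no change gave 0 calls. These simulations drew every gene independently of the others, so they do not give the rate of false calls in the real libraries.

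For 38 gene lists, camera in limma 3.58.1 compared the members' log2 CPM (prior count 2) with all other tested genes at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, camera with a prior count of 0.5 and fry, which asks only whether a list's genes move on balance in the same direction, were alternatives. A list score is the mean log2 CPM of the tested members in a library. Counts of changed members are given over all tested genes and adjusted over the list alone. On simulated data with a raised cholesterol list, camera called that list and 0 others. The simulated genes varied independently, while real members of many lists move together, so this does not give camera's rate of false calls here. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, apart from those described here as added.

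The rule named Tcf7l2, Tcf7, Tcf7l1 and Lef1, then the 12 largest rises and the 12 largest falls among changed genes with an average log2 CPM of at least 1 and a symbol that is not a Gm number or a Rik clone name. It also took up to 4 members of smallest p from each list, and Adipoq, Lep, Pparg, Ucp1, Slc2a4 and Adgre1 in any case. This gave 168 genes. Single-gene results of some of them are not reported here. Other genes named in the text were chosen after their values were seen.

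The alternatives fixed beforehand were RLE factors, upper-quartile factors, library size alone, no filter, a stricter filter, DESeq2 1.42.0, limma-voom with quality weights, robust dispersions, an adjusted p below 0.1, glmTreat against a fold of 1.2, 1 surrogate variable from sva 3.50.0, removal of mitochondrial and haemoglobin genes, and leaving out each library in turn. Added after the data were seen were the B cell and muscle scores as covariates, the intronic-type score as covariate, offsets that remove each library's trend with exonic length and GC content, control 5 and knockout 1 left out together, and protein-coding genes alone. The intronic-type score is the mean log2 CPM of genes that the annotation classes as TEC (single-exon models still to be tested experimentally) or as sense-intronic. Processed pseudogenes were matched to their parent genes with BLAST 2.17.0+. Plots and annotation tables were made with Python 3.11.15.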

Results

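Gene counts were obtained by RNA sequencing from inguinal white adipose tissue, a subcutaneous fat depot, of C57BL/6 mice at 6 months of age that had been fed a 65% high-fat diet. The 5 control libraries came from mice with floxed Tcf7l2 alleles, and the 5 knockout libraries from mice that carried in addition a Cre recombinase directed to fat. Total counts were 16587360, 15352970, 16307376, 14032866 and 17782073 in control 1 to 5 and 17047144, 16761541, 15205688, 15010152 and 15681876 in knockout 1 to 5. Depth did not separate the groups (exact permutation p = 0.944, n = 5 per group), and between 25826 and 29461 genes had counts in a library. The first principal component of the 500 most variable genes held 49.0% of their variance. It placed controls 1 to 4 between -22.7 and -12.0 and the knockouts between 3.96 and 35.6, with control 5 at 5.99, inside the knockout range (exact permutation p = 0.024, adjusted p = 0.116). Knockout 1 lay at the far end of that axis.

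The comparison asked which transcripts differ when Tcf7l2, a transcription factor that acts with beta-catenin in Wnt signalling, is deleted in the adipocytes of mice on a high-fat diet. Tcf7l2 itself (ENSMUSG00000024985, GRCm38 chromosome 19, 55741820 to 55933654, plus strand, protein-coding) fell in the knockout to 54.7% of the control level. Its CPM was 10.7 ± 0.909 in the controls and 5.83 ± 0.311 in the knockouts (mean ± SD, n = 5 each), a log2 fold change of -0.87 (SE 0.096, adjusted p = 6.1e-04). The ranges did not overlap, 9.16 to 11.4 CPM in controls and 5.57 to 6.20 CPM in knockouts, and the exact permutation p was 0.0079, the smallest this design can give. The values rest on between 83 and 190 counts per library. By library they were 11.1, 10.5, 9.16, 11.4 and 11.1 CPM in control 1 to 5 and 5.57, 6.14, 6.20, 5.58 and 5.68 CPM in knockout 1 to 5, so every library followed its label. The position of the deleted exon is not given in the sources used here, and counts from the rest of the gene or from cells other than adipocytes remain in these values.

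In the knockout, 11 of 18 endothelial markers were lower, while 8 of 22 genes of cholesterol synthesis and 10 of 18 T cell markers were higher. The camera calls for lists of endothelial, Schwann cell, cholesterol synthesis, ribosomal protein, cell cycle and T cell genes all had an adjusted p of 0.721 with an estimated correlation, and that for B cell markers 0.755. Of the genes named by size, Cyp2e1, which oxidises ketones and small foreign molecules, fell from 88.4 ± 47.5 to 15.7 ± 3.04 CPM (log2 fold change -2.50, SE 0.35, adjusted p = 0.0023). Erbb4, a receptor for neuregulins, fell from 4.23 ± 1.75 to 0.607 ± 0.388 CPM (log2 fold change -2.80, SE 0.41, adjusted p = 0.0030). Vat1l at -2.03 (adjusted p = 3.0e-04), the pantetheinase gene Vnn1 at -1.76 (adjusted p = 7.0e-04) and Cbs, whose enzyme joins homocysteine and serine, at -1.61 (adjusted p = 3.6e-04) fell as well, and all 5 kept their call whichever library was left out. In all, 2053 of 15927 tested genes changed (12.9%), 930 higher and 1123 lower, and 4930 had an unadjusted p below 0.05. Library numbers run from 1 to 5 in controls and from 6 to 10 in knockouts. For every call, genotype therefore cannot be told apart from RNA handling or library preparation that followed this order. The median fold of the changed genes was 1.36, and 96 higher and 260 lower genes changed at least 2-fold. The number of changed genes moved with single libraries. It was 560 without control 1, 537 without control 2, 903 without control 4, 998 without knockout 2 and 885 without knockout 5, against 3094 without control 5. Of the 99 changed genes among the 168 named by the rule, 37 passed in each of the 10 fits that left out 1 library. With a score of intronic-type transcripts as a covariate, given with the last group, 49 genes passed, and no list had more than 2 called members.

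**Figure D1:**
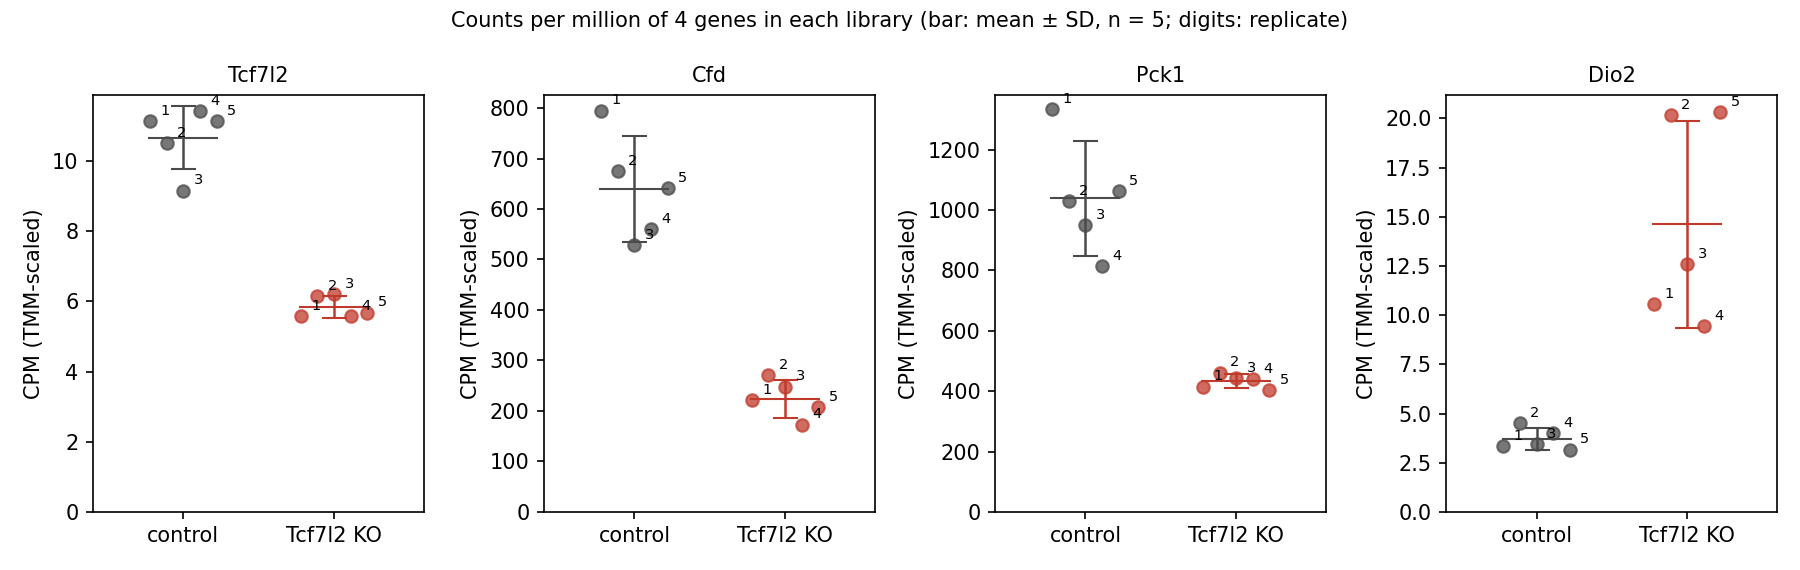
Expression of Tcf7l2, Cfd, Pck1 and Dio2 in CPM on linear axes from 0, with a point for each of the 5 control and 5 knockout libraries and bars at the mean with SD. Tcf7l2 averages 10.7 in controls and 5.83 in knockouts, Cfd 640 and 224, Pck1 1038 and 433, and Dio2 3.69 and 14.6, and no control library overlaps a knockout library.

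Among 20 mature adipocyte markers, 1 was higher, 6 were lower and 13 did not pass, and adjusted over the list alone 2 were higher and 6 lower (median log2 fold change -0.04, camera adjusted p = 0.193, and -0.19 and 0.0015 with the intronic-type score as a covariate). Cfd, which encodes the secreted protease adipsin, fell from 640 ± 105 to 224 ± 37.7 CPM (log2 fold change -1.51, SE 0.13, adjusted p = 1.5e-04). Slc2a4, the insulin-responsive glucose transporter, fell from 77.0 ± 7.05 to 52.5 ± 4.99 CPM (log2 fold change -0.55, SE 0.081, adjusted p = 0.0030). The adiponectin gene Adipoq, at 2989 ± 252 and 2976 ± 432 CPM (adjusted p = 0.975), did not pass. Nor did Pparg, the master regulator of fat cell formation, at a log2 fold change of -0.13 (adjusted p = 0.352). The leptin gene Lep rose from 4089 ± 703 to 5689 ± 533 CPM (adjusted p = 0.024), a call lost without control 1, control 2, control 4, knockout 2 or knockout 5 (adjusted p up to 0.081). The number of lower markers was 2 without control 1, control 2 or knockout 4 and 3 without control 3 or knockouts 1, 2, 3 or 5, and that of higher markers was 2 without control 5 or knockouts 1 or 4. Of 12 genes linked to adipose expansion in obesity, 1 was higher (Lep), 4 were lower and 7 did not pass, and adjusted over the list alone 3 were higher and 4 lower. The median was 0.06, while the mean of -0.03 and the camera direction were negative (adjusted p = 0.925). Car3, an abundant carbonic anhydrase of fat, fell from 10825 ± 1572 to 7116 ± 541 CPM (adjusted p = 0.0075) and the amino acid transporter gene Slc7a10 fell by 0.37 on the log2 scale (adjusted p = 0.0096). Without control 2 the lower count of this list was 2, and without control 5 or knockout 1 its higher count was 2. In the insulin signalling list, Slc2a4 and Grb14, an adaptor that restrains the insulin receptor (-0.39, adjusted p = 0.025), were lower, 0 were higher and 22 of 24 did not pass. Adjusted over the list alone the same numbers resulted, 0 higher and 2 lower (median -0.06, camera adjusted p = 0.104), and Grb14 was lost without control 1, control 3 or knockout 3, which leaves 1.

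Lipid synthesis genes moved in both directions. In the triglyceride list, 5 of 17 were higher, 2 lower and 10 did not pass, with 5 and 2 adjusted over the list alone (median 0.07, camera adjusted p = 0.185). Pck1, whose enzyme supplies the glycerol backbone from pyruvate, fell from 1038 ± 191 to 433 ± 23.3 CPM (log2 fold change -1.26, SE 0.11, adjusted p = 1.5e-04), and Mogat1, an acyltransferase, fell from 9.46 ± 1.36 to 3.26 ± 0.840 CPM (-1.53, adjusted p = 6.4e-04). Gk, the glycerol kinase gene, rose from 37.1 to 71.0 CPM (0.94, adjusted p = 0.0030). A single member was higher when control 1, 2 or 4 or knockout 2, 3 or 5 was left out. De novo lipogenesis had 3 higher, 1 lower and 17 not passing of 21, with 3 and 1 adjusted over the list alone (median 0.11, camera adjusted p = 0.104). Elovl5, a fatty acid elongase, rose by 0.32 (adjusted p = 0.011) in every leave-out fit, Fasn rose by 0.46 (adjusted p = 0.039, in 2 of 10 such fits) and Thrsp fell by 0.71 (adjusted p = 0.037, in 4 of 10). The higher count was 1 without control 1, 2 or 4 or knockout 2 and 5 without knockout 4, and the lower count was 0 without control 1, 2 or 3 or knockout 3 or 4. Lipolysis and fatty acid handling had 1 higher, Hilpda (0.85, adjusted p = 0.039), 2 lower, Adrb3 (-1.52, adjusted p = 0.036) and Aqp7 (-0.35, adjusted p = 0.046), and 19 not passing of 22, and the same 1 and 2 adjusted over the list alone. Its median of 0.06 and camera direction were positive (adjusted p = 0.461) and its mean, -0.01, was negative. Adrb3 encodes the beta-adrenergic receptor of fat cells and Aqp7 a glycerol channel, and 0 members were lower without control 1 or 2 or knockout 1, 3, 4 or 5 and 1 without control 3 or 4 or knockout 2. Hilpda was lost without any of the controls 1 to 4 or knockouts 1, 2, 3 and 5 (adjusted p up to 0.102), and without knockout 4 the list had 4 higher members.

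Cholesterol biosynthesis had 8 higher, 0 lower and 14 not passing of 22, and 13 higher and 1 lower adjusted over the list alone. Lss, the enzyme that closes the sterol rings, rose by 0.53 (SE 0.086, adjusted p = 0.0051), Cyp51 by 0.50 (adjusted p = 0.011), Idi1 by 0.44 (adjusted p = 0.012) and Hsd17b7 by 0.39 (adjusted p = 0.013), and these 4 passed in every leave-out fit. The list was called higher by camera (median 0.29, adjusted p = 8.4e-06), and its adjusted p was 0.721 with an estimated correlation. Without knockout 1, 1 member was lower.

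Of 44 nuclear-encoded oxidative phosphorylation genes, 3 were higher (Ndufb3 at 0.34, Uqcrq at 0.29 and Atp5o at 0.28), 0 were lower and 41 did not pass. Adjusted over the list alone 0 passed by edgeR, 14 had an unadjusted p below 0.05, and DESeq2 called 6 and limma-voom 7 over all genes. Camera called the list higher (median 0.12, adjusted p = 5.8e-04), with an adjusted p of 0.797 with an estimated correlation and 0.448 with length and GC offsets. With the intronic-type score as a covariate the call was lost and the direction turned (median -0.03, adjusted p = 0.667). The count was 0 without control 1, 2 or 4 or knockout 2 or 5, 1 without control 3 or knockout 3, and 6 without knockout 4. The mitochondrially encoded transcripts went the other way, with 2 of 10 lower (mt-Nd4 at -0.54 and mt-Nd6 at -0.68), 0 higher and 8 not passing, and 6 lower and 0 higher adjusted over the list alone. Camera called them lower (median -0.44, adjusted p = 0.049), with an adjusted p of 0.797 with an estimated correlation and 0.0505 with a prior count of 0.5. Its adjusted p was 0.079, 0.054 and 0.247 without control 1, 3 and 5 and 0.097, 0.060, 0.078 and 0.082 without knockout 1, 2, 3 and 4. The count of lower members was 0 without control 1, 2, 3 or 5 or knockout 2, 3 or 4, 1 without knockout 1 or 5, and 4 without control 4.

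Fatty acid oxidation had 0 higher and 0 lower members of 23 by edgeR over all genes and over the list alone (median 0.06, camera adjusted p = 0.342), 4 with an unadjusted p below 0.05, 0 by DESeq2 and 1 by limma-voom. Without knockout 1 or 4, 1 was higher. Of 22 genes of the TCA cycle, 1 was lower, Idh2 (-0.32, adjusted p = 0.020, lost without control 1 at 0.053), 0 were higher and 21 did not pass, with the same 0 and 1 adjusted over the list alone (median 0.08, camera adjusted p = 0.320), and 1 was higher without knockout 1 or 4. Camera called this list higher with 1 surrogate variable (adjusted p = 0.034) and with the B cell and muscle scores as covariates (adjusted p = 0.0068), and lower with the intronic-type score as a covariate (median -0.08, adjusted p = 0.024). Glycolysis had 5 higher, 1 lower and 10 not passing of 16, with 6 higher and 1 lower adjusted over the list alone. Aldoa, the aldolase gene, rose by 0.47 (adjusted p = 0.011), Pkm, for pyruvate kinase, rose by 0.33 (adjusted p = 0.021), and Ldhb, which encodes a lactate dehydrogenase subunit, fell by 0.68 (adjusted p = 0.0017). Pkm was lost without control 1, 2 or 4 (adjusted p up to 0.064). By camera the list was higher (median 0.16, adjusted p = 0.038), with an adjusted p of 0.755 with an estimated correlation. That call was lost without control 2 (0.056), control 4 (0.070) or knockout 3 (0.057), with 1 surrogate variable (0.073) and with the intronic-type score as a covariate (median 0.00013, adjusted p = 0.877). The higher count was 1 without control 1, 2 or 4 and 2 without knockout 2 or 5.

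The thermogenic list held some of the clearest rises and had both directions, with 6 higher, 2 lower and 11 not passing of 19, and 6 and 4 adjusted over the list alone (median 0.14, camera adjusted p = 0.070). Dio2, which activates thyroid hormone, rose from 3.69 ± 0.557 to 14.6 ± 5.27 CPM (log2 fold change 1.99, SE 0.23, adjusted p = 6.7e-04). Elovl3, a fatty acid elongase of brown fat, rose from 2.21 ± 0.588 to 10.6 ± 6.44 CPM (2.25, SE 0.38, adjusted p = 0.0063), and the proton channel gene Otop1 rose from 30.4 to 53.7 CPM (0.82, adjusted p = 0.0013). The lower members were Cidea, a lipid droplet protein gene (-1.12, adjusted p = 0.022), and Ebf2, a regulator of brown fat cell fate (-0.39, adjusted p = 0.024). The uncoupling protein gene Ucp1 stood at 2.41 and 4.65 CPM (0.94, adjusted p = 0.182). Without control 1 or 2 the list had 3 higher and 0 lower members, and it had 1 lower member without control 4, knockout 2 or knockout 5. In branched-chain amino acid catabolism 1 gene was higher, 4 were lower and 17 did not pass of 22, and 2 were higher and 6 lower adjusted over the list alone (median -0.14, camera adjusted p = 0.055). Ivd, the isovaleryl-CoA dehydrogenase gene, fell from 135 to 87.4 CPM (-0.63, SE 0.069, adjusted p = 6.1e-04), while Bckdhb, for a subunit of the branched-chain ketoacid dehydrogenase, rose (0.75, SE 0.085, adjusted p = 6.4e-04). Without control 1 or 2 the lower count was 2, without knockout 1 the higher count was 2, and with length and GC offsets 7 were lower. The hypoxia list had 3 higher, 2 lower and 10 not passing of 15, with 4 and 3 adjusted over the list alone (median 0.05, camera adjusted p = 0.468). Egln3, an oxygen-sensing prolyl hydroxylase, rose by 1.28 (adjusted p = 0.011) and Ndrg1 fell by 0.46 (adjusted p = 0.012), both in every leave-out fit. Its higher count was 1 without control 1, 2 or 4 or knockout 2 or 5, and its lower count was 1 without any of the controls 1 to 4 or knockouts 2 to 5.

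**Figure D2:**
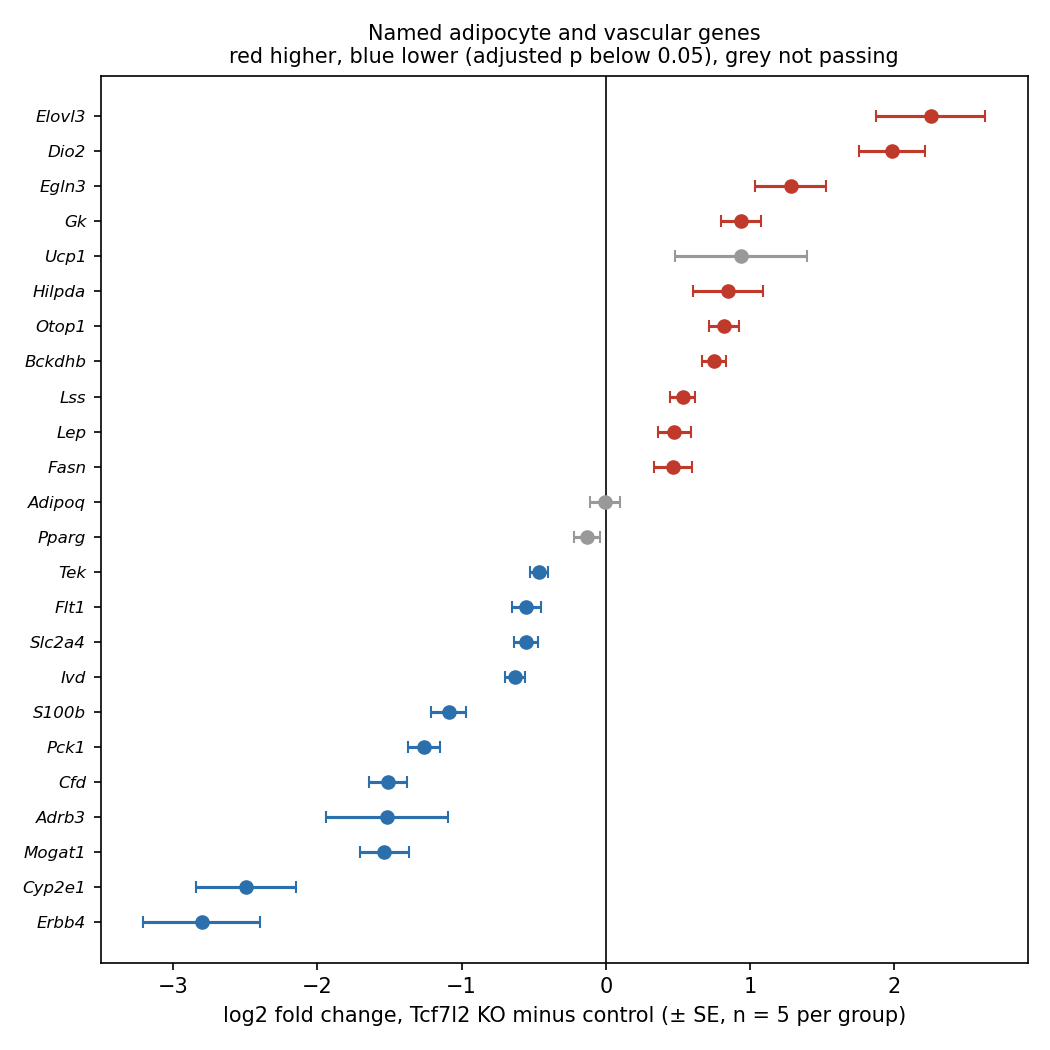
Log2 fold changes of 24 named genes, knockout over control, as points with SE bars, n = 5 libraries per group, coloured red for higher, blue for lower and grey for not passing. Erbb4 and Cyp2e1 lie lowest at -2.80 and -2.50, while Ucp1, Adipoq and Pparg did not pass.

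In the TCF/LEF family, 2 of 4 genes were higher, 1 was lower and 1 did not pass, and adjusted over the list alone 2 were higher and 2 lower. Beside Tcf7l2, its paralogs Tcf7 (6.53 ± 8.31 CPM in knockouts, log2 fold change 2.33, SE 0.70, adjusted p = 0.046) and Lef1 (3.19 ± 4.14 CPM in knockouts, log2 fold change 2.62, SE 0.75, adjusted p = 0.040) rose, and Tcf7l1 stood at -0.41 (adjusted p = 0.087). Knockout 1 held 21.1 CPM of Tcf7 and 10.5 CPM of Lef1, and without it their log2 fold changes were 1.14 and 1.37 (adjusted p = 0.082 and 0.059). Knockout 2, whose T cell score of 1.10 was the lowest of the knockouts, held 0.608 CPM of Tcf7 and 0.426 CPM of Lef1, both below the mean of the controls. The higher count was 0 without controls 1, 2, 3 or 4 or knockouts 1 or 5, and 1 without control 5 or knockout 4. It was also 0 by limma-voom with quality weights and, by edgeR, with 1 surrogate variable, the B cell and muscle scores or the intronic-type score, and 1 with length and GC offsets. The list's median of 0.96 and mean of 0.92 were positive while camera gave the direction down (adjusted p = 0.383). Fry called the list lower (adjusted p = 0.013). The list holds the deleted gene Tcf7l2 itself, so that call does not show that the other members fell. Of 18 Wnt target genes, 3 were higher (Tcf7, Lef1 and Nkd1), 1 was lower and 14 did not pass, with 5 and 1 adjusted over the list alone (median 0.19, camera adjusted p = 0.186). Nkd1, an inhibitor induced by the pathway, rose by 0.51 (adjusted p = 0.017, lost without control 1 or 2 at up to 0.054) and Apcdd1, another inhibitor, fell by 0.47 (adjusted p = 0.0042). The higher count was 0 without control 1 or 2 and 1 without control 3, control 4, knockout 1 or knockout 5. It was 1 with the B cell and muscle scores as covariates and 0 with 1 surrogate variable or the intronic-type score. Of 26 Wnt receptors and mediators 0 passed by edgeR over all genes or over the list alone, 3 had an unadjusted p below 0.05, and DESeq2 and limma-voom called 1 each. Their median was 0.00090 and their mean -0.02 (camera adjusted p = 0.759, direction down).

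Lymphocyte transcripts were higher on average in the knockout group and highest in knockout 1, and the groups overlapped. The T cell score of knockout 2 (1.10) lay below that of control 5 (1.42). The B cell scores of knockouts 2 and 3 (2.34 and 2.19) lay below that of control 3 (2.68). Of 18 T cell markers 10 were higher, 0 lower and 8 did not pass, with 14 and 0 adjusted over the list alone. The T cell receptor complex genes Cd3d (2.14, adjusted p = 0.025) and Cd3g (2.01, adjusted p = 0.027), the cytotoxic T cell gene Cd8b1 (2.44, adjusted p = 0.028) and the adaptor gene Skap1 (2.13, adjusted p = 0.021) rose. The list was called higher by camera (median 1.71, adjusted p = 8.4e-06), with an adjusted p of 0.721 with an estimated correlation. Of 14 B cell markers, 6 were higher, 1 was lower (Ebf1, at -0.27, also expressed by fat cells) and 7 did not pass, with 13 and 1 adjusted over the list alone. In the camera test the list was higher (median 2.70, adjusted p = 0.0021), with an adjusted p of 0.755 with an estimated correlation. The largest rise among the genes named by size was that of Ms4a1, the B cell surface protein CD20 (2.06 to 24.3 CPM, log2 fold change 3.56, SE 0.98, adjusted p = 0.035). The 12 largest rises were all of genes active in lymphocytes, with the highest level in knockout 1, namely Ms4a1, Fcmr (3.52), Tnfrsf13c (3.19), Ly6d (3.16), Spib (3.08), Treml2 (3.04), Iglc3 (2.98), Cxcr5 (2.86), Pax5 (2.85), Cd79a (2.85), Pou2af1 (2.81) and Cd79b (2.72). Without knockout 1, 3 of these 12 passed, Ms4a1 at 1.52 (adjusted p = 0.045), Treml2 at 1.35 (adjusted p = 0.045) and Cd79b at 1.04 (adjusted p = 0.037). The T cell count was 0 without control 1 or 2, 1 without control 4, 4 without control 3 and 5 without knockout 5. The B cell count was 0 without control 1, 2 or 4, 1 without knockout 5, and 3 without control 3, control 5 or knockout 1. Ebf1 was lost without any 1 of controls 1, 2 and 4 or the knockouts. Limma-voom with quality weights called 6 T cell and 1 B cell markers higher. With the B cell and muscle scores as covariates, which hold some of these genes, the camera adjusted p was 0.076 for the T cell and 0.727 for the B cell list.

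Macrophage markers showed no change past the threshold. Of 23, 0 passed by edgeR over all genes or over the list alone, 0 had an unadjusted p below 0.05, and DESeq2 and limma-voom called 0 (median -0.02, camera adjusted p = 0.877). Adgre1, the F4/80 antigen of macrophages, had a log2 fold change of -0.12 (adjusted p = 0.380) and Csf1r, the receptor for their growth factor, -0.11 (adjusted p = 0.245). Among 25 cytokines and chemokines, Ccl5, a T cell chemokine, rose by 0.92 (adjusted p = 0.030), 0 were lower and 24 did not pass. Adjusted over the list alone 0 passed by edgeR, 3 had an unadjusted p below 0.05, and DESeq2 called 2 and limma-voom 3 (median 0.20, camera adjusted p = 0.062). The count was 0 without controls 1, 2, 3 or 4 or knockout 3, 4 without control 5 and 2 without knockout 1. Camera called the list higher with library size alone (adjusted p = 0.031) and with no filter (0.013). It also did so without control 5 (0.0050), knockout 2 (0.044) or knockout 5 (0.027). Of 18 interferon-stimulated genes 0 passed by edgeR over all genes or over the list alone, 3 had an unadjusted p below 0.05, DESeq2 called 0 and limma-voom 1 (median -0.18, camera adjusted p = 0.073). Without control 5, 1 was lower.

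Of 18 endothelial markers, 11 were lower, 0 were higher and 7 did not pass, with 13 lower and 0 higher adjusted over the list alone. Tek, the angiopoietin receptor gene, fell from 112 ± 6.21 to 81.0 ± 5.92 CPM (log2 fold change -0.46, SE 0.063, adjusted p = 0.0020). The VEGF receptor genes Flt1 (-0.55, adjusted p = 0.0093) and Kdr (-0.44, adjusted p = 0.017) and the junction gene Cdh5 (-0.40, adjusted p = 0.015) fell too, and these 4 passed in every leave-out fit. The endothelial score, a mean log2 CPM, was 5.88 ± 0.09 in controls and 5.60 ± 0.08 in knockouts, lower in all 5 knockouts than in any control (exact permutation p = 0.0079, adjusted p = 0.086). That p is the smallest the test can give, so the adjusted value depends on how many other lists reach it. Camera called the list lower (median -0.36, adjusted p = 8.4e-06), with an adjusted p of 0.721 with an estimated correlation. The number of lower members was 4 without control 1, 6 without control 2, 7 without control 3, control 4 or knockout 3, and 5 without knockout 5. It was 1 with the B cell and muscle scores as covariates, where the median was -0.30 and camera at the preset correlation kept its call (adjusted p = 3.3e-04). Among 11 pericyte and smooth muscle markers, Lmod1 (-0.57, adjusted p = 0.034) and Abcc9 (-0.31, adjusted p = 0.041) were lower, 0 were higher and 9 did not pass, and adjusted over the list alone 5 were lower and 1 higher (median -0.26, camera adjusted p = 0.129). None was lower without controls 1, 2 or 3 or knockouts 2 or 5, 1 was without control 4 or knockouts 1 or 3, and 4 were without control 5.

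Of 8 Schwann cell and nerve markers, 4 were lower, 0 were higher and 4 did not pass, with 5 lower and 0 higher adjusted over the list alone. S100b, a calcium-binding protein gene of glia that fat cells also express, fell from 13.8 ± 2.10 to 6.50 ± 0.714 CPM (-1.09, SE 0.12, adjusted p = 6.4e-04). The myelin gene Prx (-0.90, adjusted p = 0.046) fell as well, in 2 of the 10 leave-out fits. Camera called the list lower (median -0.80, adjusted p = 0.014), with an adjusted p of 0.721 with an estimated correlation and 0.085 without knockout 1. The call was lost too with the intronic-type score as a covariate (median 0.0049, adjusted p = 0.629), with 1 surrogate variable (0.051) and with the B cell and muscle scores (0.169). The count was 1, S100b, without control 1, 2 or 4 or knockout 5, and 2 without knockout 1, 2 or 4. Extracellular matrix genes had 1 of 28 higher, Col6a2, a collagen chain (0.32, adjusted p = 0.049), 0 lower and 27 not passing. Adjusted over the list alone 0 passed by edgeR, 5 had an unadjusted p below 0.05, DESeq2 called 2 higher and 1 lower and limma-voom 1 and 1 (median 0.12, camera adjusted p = 0.104). The Col6a2 call was lost without controls 1 to 4 or knockouts 1, 2, 4 or 5, and 2 members were higher without control 5 or knockout 3. Of 19 progenitor and fibroblast markers, F3 (-0.47, adjusted p = 0.021) and Creb5 (-0.52, adjusted p = 0.036) were lower, 0 were higher and 17 did not pass, with the same 0 and 2 adjusted over the list alone (median -0.08, camera adjusted p = 0.383). The lower count was 0 without control 1 and 1 without control 2, 4 or 5 or knockout 2, 4 or 5, and 2 were higher without control 5 and 1 without knockout 4.

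All 13 skeletal muscle markers had positive fold changes (median 1.28) and 0 passed by edgeR over all genes or over the list alone, 0 had an unadjusted p below 0.05, DESeq2 called 0 and limma-voom 1 (camera adjusted p = 0.062). The muscle score was 0.57, 0.66, 0.59, 3.15 and 5.17 in control 1 to 5 and 5.88, 3.37, 5.52, 1.34 and 1.97 in knockout 1 to 5, and without control 5 there were 7 higher members. The fast-fibre genes Pvalb (1.23, adjusted p = 0.193) and Tnnt3 (1.70, adjusted p = 0.377) did not pass. Of 4 mammary epithelium markers 1 was lower, Trp63 (-0.75, adjusted p = 0.045), 0 were higher and 3 did not pass, with the same 0 and 1 adjusted over the list alone. Its median was 0.15, while its mean of -0.01 and the camera direction were negative (adjusted p = 0.914), and Trp63 passed only without control 5 or knockout 3. Of 4 skin markers 1 was higher, the desmosome gene Dsg1a (0.84, adjusted p = 0.016, above all controls in all 5 knockouts), 0 were lower and 3 did not pass, with the same 1 and 0 adjusted over the list alone (median -0.13, mean 0.07, camera direction up, adjusted p = 0.652). Of 9 erythrocyte markers 0 passed by edgeR over all genes or over the list alone, 1 had an unadjusted p below 0.05, and DESeq2 and limma-voom called 0 (median -0.21, camera adjusted p = 0.160).

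**Figure D3:**
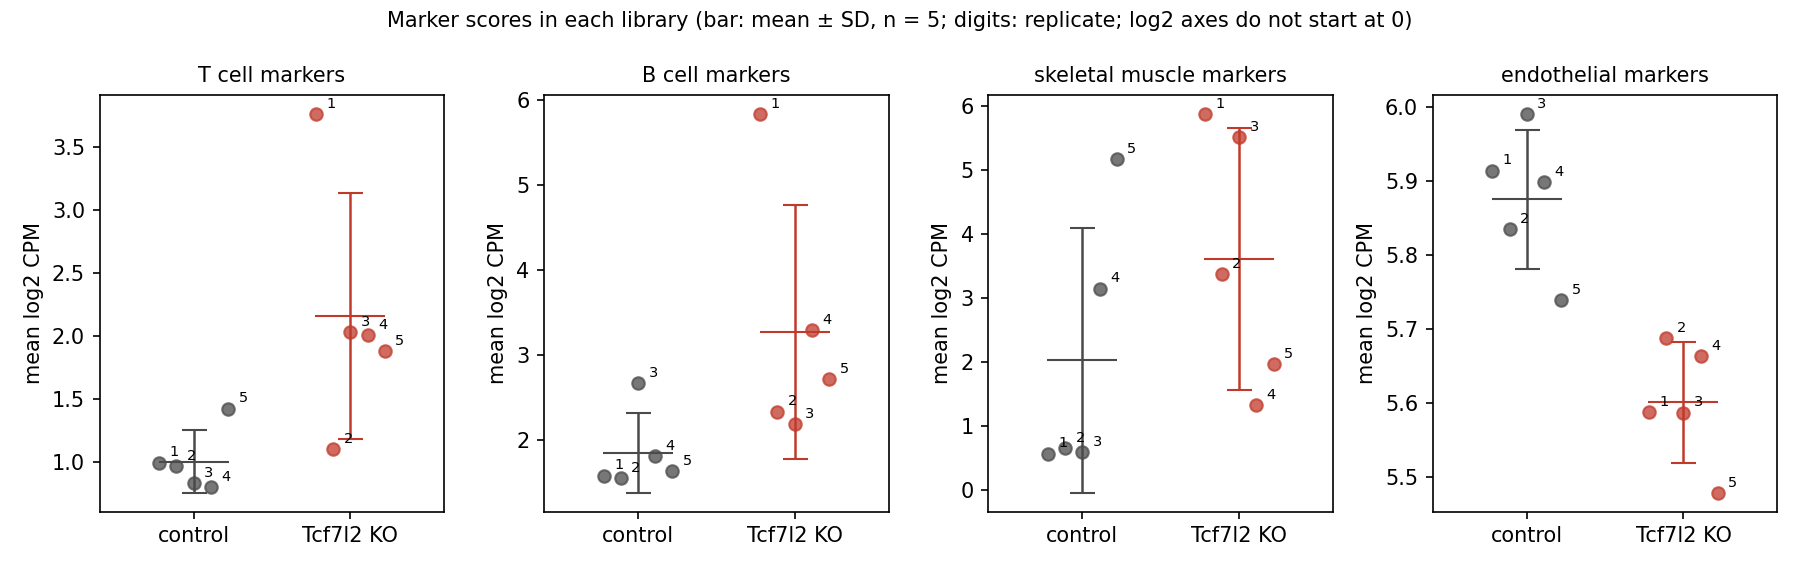
T cell, B cell, muscle and endothelial scores, each the mean log2 CPM of the list's tested members, with a point per library for the 5 controls and 5 knockouts, on log2 axes that do not start at 0. Knockout 1 has the highest T cell score (3.76) and B cell score (5.83), control 5 has a muscle score of 5.17 among the controls, and the endothelial scores of the groups do not overlap.

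Ribosomal protein genes gave the lowest list p by camera at the preset correlation, though not with an estimated correlation or by fry. All 34 had positive fold changes, 15 were higher, 0 were lower and 19 did not pass, and adjusted over the list alone 31 were higher and 0 lower. Rpl38 (0.34, adjusted p = 0.018), Rpl32 (0.33, adjusted p = 0.019) and Rpl14 (0.35, adjusted p = 0.022), all of the large subunit, rose by small amounts. Camera called the list higher (median 0.28, adjusted p = 3.0e-11), with an adjusted p of 0.721 with an estimated correlation. The count was 0 without control 1 or 2, 3 without control 4, 7 without knockout 2 and 2 without knockout 5, and 1 of the 34 passed with length and GC offsets (median 0.16). None passed with the B cell and muscle scores (median 0.13), the intronic-type score (median 0.18) or 1 surrogate variable (median 0.20). Camera at the preset correlation kept its call in each (adjusted p up to 3.3e-04), which does not exclude chance. Of 100 splits of the libraries, 63 called as many lists as the real one, itself included. Knockout 1, the library richest in lymphocyte transcripts, had the highest ribosomal score, 8.26. All 17 cell cycle genes had positive fold changes, 2 were higher, 0 were lower and 15 did not pass, and 11 were higher and 0 lower adjusted over the list alone. Tk1, for thymidine kinase, rose by 0.38 (adjusted p = 0.034) and Pcna, the clamp of replicating polymerase, by 0.20 (adjusted p = 0.039). By camera the list was higher (median 0.26, adjusted p = 3.6e-05), with an adjusted p of 0.721 with an estimated correlation, and 0 genes passed without control 1 or 2 or knockout 2 or 4 and 1 without control 3 or 4 or knockout 3 or 5. Of 17 clock genes, 1 was lower, 0 were higher and 16 did not pass, with the same 0 and 1 adjusted over the list alone (median -0.22, camera adjusted p = 0.115). The lower count was 0 without control 1 or 4, 2 without control 3 and 3 without control 5.

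Of 15 immediate-early and dissection stress genes 0 passed by edgeR over all genes or over the list alone, 0 had an unadjusted p below 0.05, and DESeq2 and limma-voom called 0. Their median was -0.05 and their mean 0.01 (camera adjusted p = 0.991, direction up). Of 19 genes of the unfolded protein response 0 passed by edgeR over all genes or over the list alone, 4 had an unadjusted p below 0.05, DESeq2 called 0, and limma-voom called 1 higher and 1 lower. Their median was 0.0019 and their mean -8.8e-05 (camera adjusted p = 0.998, direction up, with fry giving down), and 1 was higher without knockout 1 and 1 lower without knockout 5. Of 4 sex-linked transcripts, Kdm5d, a Y-linked demethylase gene, fell by 0.32 (adjusted p = 0.019, lost without control 2 at 0.053), 0 were higher and 3 did not pass, and 0 were higher and 2 lower adjusted over the list alone (median -0.08, camera adjusted p = 0.461). Without control 5, 2 were lower. Over the 38 lists, camera called 10, with 7 higher and 3 lower. With an estimated correlation it called 0, with 1 list at an unadjusted p below 0.05. Fry called 7, among them the TCF/LEF list, which holds the deleted gene. Several lists without a call gained 1 under other fits, and those that follow are not all of them. With the intronic-type score these were lower: mature adipocyte markers, obesity-linked expansion genes (adjusted p = 0.0027), insulin signalling (0.026), branched-chain amino acid catabolism (1.6e-05), erythrocyte markers (2.2e-05) and the TCA cycle. With 1 surrogate variable and with the B cell and muscle scores these were higher: de novo lipogenesis (0.0079 and 0.0041), fatty acid oxidation (0.020 and 0.0044), thermogenic genes (0.020 and 0.011) and the TCA cycle, and with the scores also triglyceride synthesis (0.031). Mitochondrially encoded transcripts lost their call in both (0.073 and 0.284). With length and GC offsets, branched-chain amino acid catabolism (0.017) and interferon-stimulated genes (0.026) were lower and extracellular matrix (0.017) and muscle genes (0.026) higher.

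**Figure D4:**
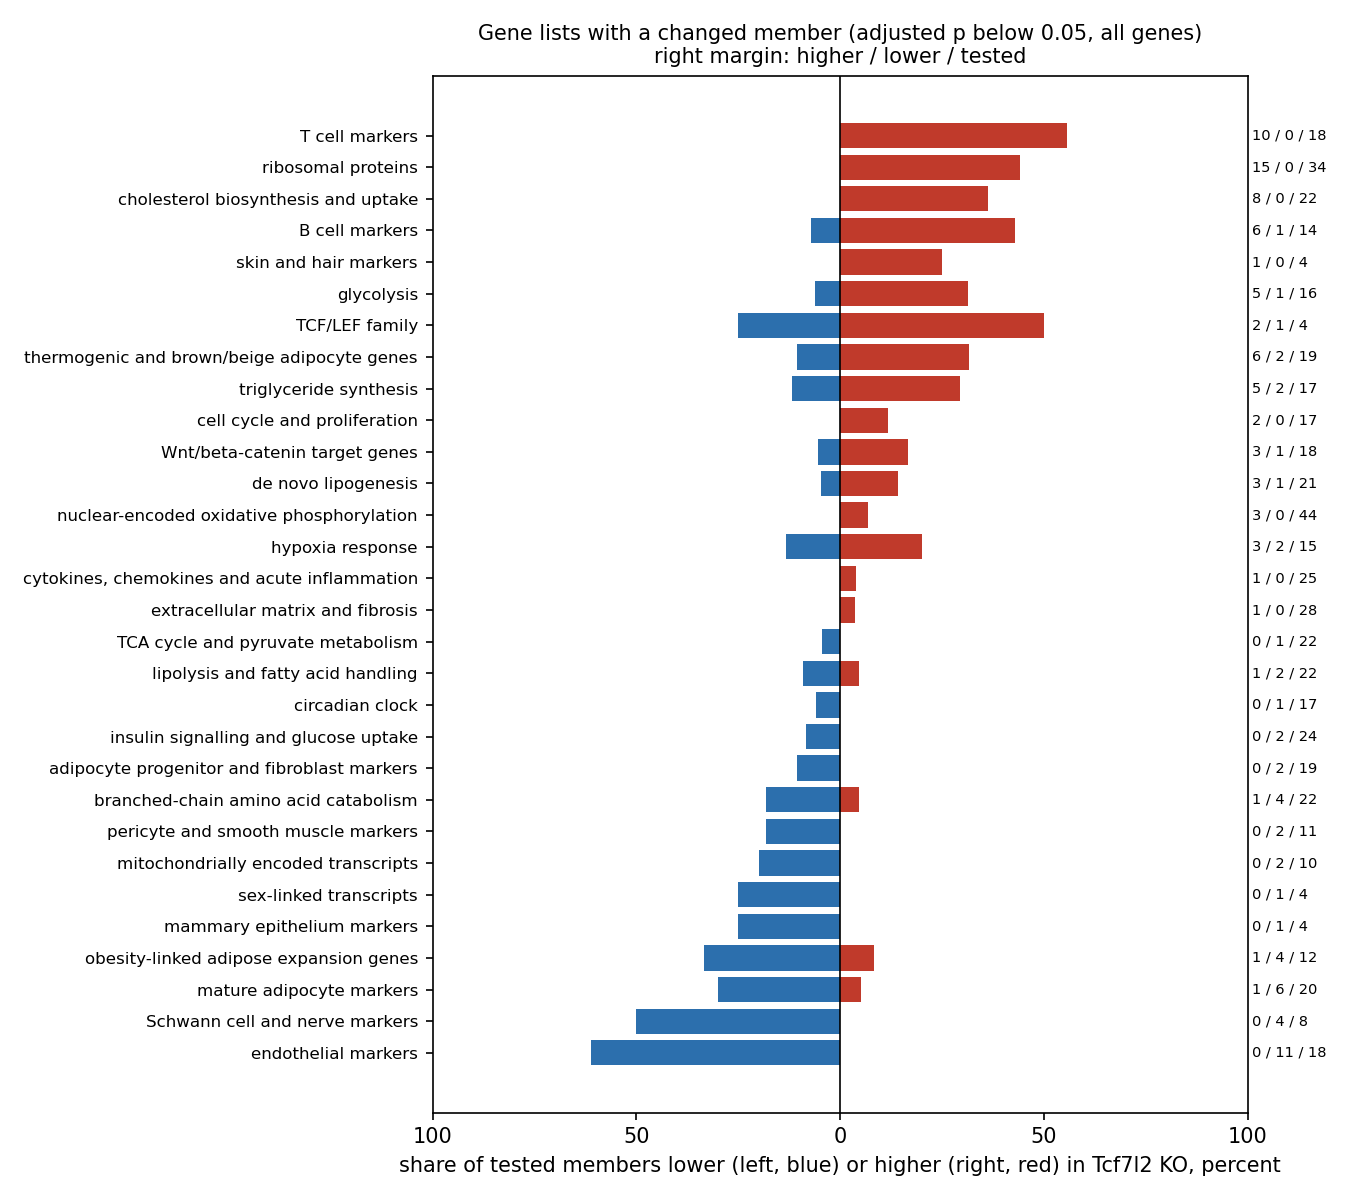
Share of tested members called higher (to the right) and lower (to the left) in the knockout, in percent, for each gene list with a changed member, with counts of higher, lower and tested members at the right margin. Endothelial markers have 11 of 18 lower, T cell markers 10 of 18 higher and ribosomal protein genes 15 of 34 higher.

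Transcripts that the annotation places inside introns, or models as a single exon of unproven status, a group chosen after the results were seen, were lower in the knockout. Of 786 such intronic-type genes, 1 was higher and 223 were lower (median log2 fold change -0.72), against 897 higher and 779 lower of 13535 protein-coding genes. Most of the 786, 700, were TEC models (192 lower), and 86 were sense-intronic (31 lower). A tested protein-coding gene that spans them on the same strand was found for 557. The mean log2 CPM of the 786, the intronic-type score, was 0.93 ± 0.37 in controls and 0.31 ± 0.17 in knockouts (n = 5 per group, with no p given because the group was picked for its fall). Control 5, at 0.38, lay inside the knockout range of 0.06 to 0.46. The number of lower intronic-type genes was 54 without control 1, 35 without control 2, 78 without control 4, 95 without knockout 2 and 84 without knockout 5, 147 without knockout 4, and 400 without control 5. It was 30 with 1 surrogate variable (median -0.65) and 13 with the B cell and muscle scores as covariates (median -0.69). The nuclear-retained RNAs Malat1 (6019 ± 1077 to 4080 ± 580 CPM, -0.56, adjusted p = 0.022) and Neat1 (363 to 237 CPM, -0.62, adjusted p = 0.012) fell too. Among protein-coding genes, the shortest of 5 groups by exonic length had 321 higher and 66 lower genes and the longest 80 higher and 335 lower. The group of lowest GC content had 141 higher and 253 lower and that of highest GC content 190 higher and 83 lower. With the intronic-type score as a covariate, 49 genes passed, 11 higher and 38 lower, and Tcf7l2 (-0.83), Pck1 (-1.27), Cfd (-1.43) and Mogat1 (-1.73) were among them.

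**Figure D5:**
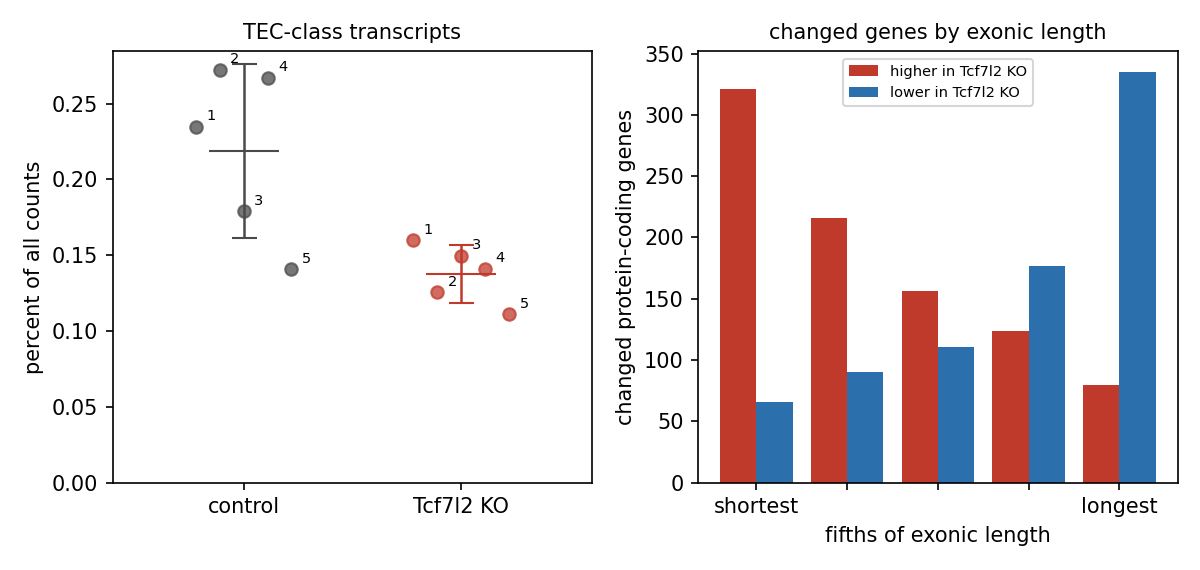
Left, share of counts in unproven single-exon models in percent, a point per library for the 5 controls and 5 knockouts; right, numbers of changed protein-coding genes, higher and lower, in 5 groups of equal size from shortest to longest exonic length. The share averages 0.219% in controls and 0.137% in knockouts, and the lower calls run from 66 in the shortest group to 335 in the longest.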

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

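In this part the tests on the T cell and B cell markers without knockout 1 were chosen after the results were seen, while the bound of the lymph node test was set before its values were looked at. A sample stood apart when its gap to the nearest other sample of its group was a larger share of the group's range than Dixon's limit for 5 samples allows. This held for 51 of 452 groups of values looked at (11.3%), where chance flags about 1 in 20 groups of normally distributed values. Of these, 23 concern knockout 1 and 8 concern control 5. Groups are not independent, since lymphocyte genes move together. The 12 largest rises were named for their size and are all highest in knockout 1, so part of its flags follows from that choice.

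Knockout 1 stood above the other knockouts in lymphocyte genes, in CPM: Ms4a1 97.8, Cd79b 85.0, Ighd 78.8, Fcmr 36.9, Cd79a 31.3, Pax5 27.3, Ly6d 24.0, Spib 23.6, Pou2af1 21.7, Tcf7 21.1, Cd3g 20.3, Cxcr5 19.4, Tnfrsf13c 16.7, Treml2 16.7, Cd8b1 14.4, Iglc3 12.9, Skap1 11.7, Lef1 10.5 and Cd3d 8.45. The next highest knockout had 9.96 CPM of Ms4a1 and 10.8 CPM of Cd79b. The same library was low in the macrophage gene Adgre1 (165 CPM, the nearest at 203) and high in Axin1 (34.3 CPM), Junb (48.5 CPM) and Rplp1 (400 CPM). Control 3 stood above the other controls in the B cell genes Ms4a1 (4.79 CPM), Fcmr (2.15 CPM), Pax5 (2.15 CPM) and Spib (1.84 CPM) and in the B cell score (2.68), and control 5 did in Iglc3 (0.996 CPM).

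For the higher lymphocyte genes of the knockout group, lymphocyte-rich tissue in knockout 1 alone would leave the markers level without it. Without knockout 1 the median log2 fold change was 0.86 for the T cell markers (exact permutation p = 0.024 for the score, 9 of 18 higher) and 0.91 for the B cell markers (exact permutation p = 0.040, 3 of 14 higher), which argues against that library as the whole source. Pieces of lymph node in the knockout tissue could bring stromal genes as well, and the summed CPM of 6 such genes had a ratio of medians, knockout over control, of 0.923 (exact permutation p = 0.817). That bound was badly chosen and does not settle the matter, because Cxcl13 made up between 71.0% and 100% of the sum and 2 of the 6 genes, Ccl21a and Ccl19, had no counts in any library. Glycam1, a gene of lymph node venules, was at 7.93 CPM in knockout 1. It was at 0.365, 0, 0.863 and 0.616 CPM in knockouts 2 to 5 and at 0.176 CPM at most in the controls. Chst4, also among the 6, was at 0.804 CPM in knockout 1 and at 0.137 CPM at most elsewhere. Madcam1, another of them, was at 0.747 CPM in knockout 1 and up to 0.615 CPM in the controls. Apart from Glycam1 in knockout 1, these values rest on few counts. Lymph node in the samples and a rise of lymphocytes in knockout fat therefore cannot be told apart.

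Control 5 stood above the other controls in the muscle genes Tnnt3 (54.0 CPM), Pvalb (37.0 CPM), Mylpf (27.5 CPM) and Actn3 (24.5 CPM), was high in Hilpda (46.6 CPM) and in the pseudogene Gm11942 (0.234 CPM), and was low in Myh11 (35.0 CPM). Control 1 held 154 CPM of the liver gene Serpina1b, with 1.22 CPM at most in the other controls, and 41.9 CPM of Irf7. Control 2 stood apart in Cldn3 (1.15 CPM), control 3 in Tpi1 (611 CPM) and Ldha (830 CPM), and control 4 in Tk1 (12.4 CPM). Knockout 2 was low in Krt10 (0.973 CPM), knockout 3 high in Egr2 (10.9 CPM) and knockout 4 low in the glycolysis score (7.10). Knockout 5 stood apart in Aldh6a1 (392 CPM), mt-Nd3 (8.28 CPM), the mitochondrially encoded score (7.51), the share of mitochondrial counts (4.10%), Tk1 (11.0 CPM, low) and the pericyte and smooth muscle score (4.27, low).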

How the results depend on the processing

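The fits with the B cell and muscle scores, the intronic-type score or length and GC offsets, without control 5 and knockout 1, and on protein-coding genes alone were chosen after seeing the data. Tcf7l2 was lower in the knockout and passed under every alternative run, at -0.92 to -0.84 when 1 library was left out. No gene that changed was called in the opposite direction under any alternative. The count of changed genes moved more: leaving out 1 library gave 537 to 3094 (227 to 1386 higher, 310 to 1708 lower), called 8 to 15 lists by camera, and gave 9 to 13 list scores with an exact permutation p below 0.05, though no score passed after adjustment in any setting (lowest adjusted p = 0.075). The smallest p of that test is 0.0079, so after adjustment over 38 lists a score passes only if several others reach that value too. DESeq2 called 2696 genes (1424 higher, 1272 lower), limma-voom with quality weights 3605 (1702 higher, 1903 lower), an adjusted p below 0.1 gave 3580 (1718 and 1862), glmTreat against a fold of 1.2 gave 121 (49 and 72) and 1 surrogate variable 700 (366 and 334). Without a filter on low counts 1313 were higher and 1026 lower, so 56.1% were higher against 45.3%, as were 52.8% with DESeq2, 52.3% with 1 surrogate variable and 59.4% with the B cell and muscle scores. The B cell and muscle scores as covariates gave 466 (277 and 189), the intronic-type score 49 (11 and 38), and leaving out control 5 and knockout 1 together 3774 (1769 and 2005). Fewer changed genes follow by construction from the fold bound. A covariate that differs between groups can lower the count as well. Leaving out libraries lowered the count in some fits and raised it in others, and the cause was not tested there or for the other settings. The estimated correlation called 0 lists, with 1 at an unadjusted p below 0.05. With the intronic-type score the fold change of Olfr734 (0.044) and the directions of the oxidative phosphorylation list (camera at 0.54, unadjusted) and the TCA cycle list (camera at 0.0077, unadjusted, called lower at an adjusted p of 0.024) reversed, and the cause was not tested. No paired analysis was possible because the labels give no shared replicate numbers. Simulated changes of 1.3-fold were mostly missed at this depth and replication, so genes that did not pass are not shown to be level.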

Other observations

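The histone gene group, the tests on intronic-type transcripts with offsets and by library number, on pseudogenes, on the genes beside Adipoq, and the counts over other splits were chosen after the results were seen, while the bound for the host genes was set before their values were looked at. Histone genes, the packaging proteins of newly made chromatin, were higher in the knockout, with 31 of 48 higher and 0 lower (median log2 fold change 0.59). Their score was 2.75 ± 0.15 in controls and 3.33 ± 0.15 in knockouts (mean ± SD of log2 CPM, n = 5 each), and no p is given because the group was picked for its rise. The count was 20 without control 2, 21 without control 1, 31 without knockout 1, 19 with length and GC offsets, 15 with the B cell and muscle scores as covariates and 3 with the intronic-type score as a covariate, by edgeR. The median was 0.45 with the B cell and muscle scores and 0.67 with the intronic-type score, so the lost calls do not show that the rise went away. Histone genes have near-identical copies and mostly lack poly(A) tails, which a library made from total RNA keeps.

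Among the 49 genes that passed with the intronic-type score as a covariate, beside those given in the report, were Hsd11b1, which regenerates active glucocorticoid (-0.94, and -1.41 with the covariate), Nnat (-1.13, and -1.19 with it), the chemerin receptor gene Cmklr1 (-0.69 and -1.11) and the carboxylesterase gene Ces1f (-1.45 and -1.52). So were Angpt1, a ligand of Tek (-1.09 and -1.18), and the Wnt inhibitor gene Sfrp5 (-0.41 and -0.72). Klf14, a regulator of fat gene expression, stood at -0.52 without the covariate, where it did not pass (adjusted p = 0.062), and at -1.02 with it. Apoc4, an apolipoprotein gene, was higher (1.77, and 2.09 with the covariate). The non-coding Gm36827 was lower at -1.78, and -2.01 with the covariate. The covariate differs between the groups, so it can also take away real differences: 1676 changed protein-coding genes kept a median share of 0.697 of their log2 fold change, their SE grew by a median factor of 1.46, and 1656 had the same sign.

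The number of changed genes was set against other splits of the 10 libraries into 5 and 5. Of 100 splits drawn from the 126 possible, 1 gave as many as 2053, the real one. The highest other split drawn, which exchanges control 5 and knockout 1, gave 469. This argues against chance for that count without excluding it, because the remaining splits were not run. It does not tell genotype from the order of the library numbers, which separates the same groups. For the number of gene lists called by camera, chance cannot be excluded: the real split called 10, the highest other 22, and 63 of the 100 splits gave as many.

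Intronic-type transcripts were lower in the knockout, 223 of 786. Lower mRNA levels of their host genes would lower both alike. Over pairs of a lowered transcript and its tested host (182 transcripts, 137 hosts), the host median log2 fold change was -0.13 (quartiles -0.28 and 0.02). The lowered transcripts had -1.09 over these pairs, a value enlarged because they were picked for their fall, while all 786 had -0.72. This argues against lower host mRNA as the whole cause, though 34 of these hosts were called lower. Transcription of the hosts was not measured, so a fall in it was not tested. The libraries' trend with exonic length and GC content is argued against as well, since 208 lower calls were made with offsets that remove it and the median was -0.80, against -0.72. A difference in RNA handling or library preparation cannot be told apart from genotype, because the library numbers run from 1 to 5 in controls and from 6 to 10 in knockouts (0 knockout numbers lie below the highest control number). A lower level of unspliced or nuclear RNA in the knockout fat, or a different yield of it, stays open.

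The largest rises of all were those of 3 processed pseudogenes, beyond all controls in each of the 5 knockouts: Gm7049 (chromosome 13, 0.550 to 15.3 CPM, log2 fold change 4.76), Gm11868 (chromosome 4, 0.471 to 6.62 CPM, 3.79) and Gm11942 (chromosome 4, 0.0838 to 3.01 CPM, 5.01). The controls held 0 to 4 counts of Gm11942, with their mean below the floor of 3 counts, so the size of its rise is not exact. Higher expression of the parents is argued against for Gm7049 and Gm11868, since the larger log2 fold change of Me1 and Cyb5r4 was 0.10, and is undecided for Gm11942, whose matched parent Gm10073 had 5 to 11 counts per library (-0.11 without the filter on low counts). Me1 and Cyb5r4 lie 326 kb apart on chromosome 9, and a share of 0.0023 of random triples of pseudogenes has a pair of parents within 500 kb, so a stretch of another haplotype there may be the source, but 7 of 30 loci, with overlapping genes joined, held a changed gene within 5 Mb of them (one-sided Fisher exact p = 0.103) and 16 of 68 within 10 Mb (0.0180), which leaves it undecided. Within 100 kb of Adipoq, 2 of 4 tested genes were higher, Rfc4 (0.90) and Eif4a2 (0.26), which overlap and may share reads, so 1 of 2 loci held a higher gene (one-sided Fisher exact p = 0.138). Kng2, outside that window on the same chromosome, rose from 0.610 to 1.39 CPM (1.18, adjusted p = 0.031) and was not part of the test. It also counts among the higher members of the thermogenic list. A candidate explanation, left open by the Fisher test, is extra copies carried with a Cre transgene built on that locus, and the labels do not give the construct.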
